A study of Caenorhabditis elegans with 24 samples.

How the data were processed

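Small RNAs of C. elegans were sequenced from 2 strains, one carrying FLAG-tagged CSR-1 and the other FLAG-tagged WAGO-9, each as wild type or with the znfx-1(ne4354) mutation. From each strain and genotype there were 3 libraries of total small RNA (the input) and 3 of small RNA recovered with the tagged Argonaute by anti-FLAG immunoprecipitation (IP), which makes 24 libraries in 8 groups. The labels describe whole worms grown as synchronous populations, small RNAs enriched with mirVana for the inputs, and treatment with the polyphosphatase PIR-1 before ligation, so that small RNAs with a 5' triphosphate were cloned. They do not say whether replicates of a group are separate cultures, so every p-value measures the spread between these samples, which may be technical.

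The submitters' processing notes name cutadapt and Bowtie2 with no version or settings, and the genome or transcript build is not given in the sources used here. Each deposited file lists 22-nt sequences that start with G, with the gene, the position on its spliced mRNA, a strand flag and a value headed ppm, which is the authors' RPM (reads scaled to a library total). Antisense alignments carry flag 16 and unmapped sequences flag 4. Unmapped sequences were listed in the IP files only, so the files of IPs and inputs were filtered differently and comparisons between them rest on antisense reads alone. A sequence listed on several identical lines had its value divided among them and was assigned by the authors to 1 gene and 1 position.

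The value of 1 read was found in each file, and values of sequences listed once were whole multiples of it in 100% of cases within 0.0056 ppm, the rounding of the files. Across libraries, 89.95% to 98.52% of all sequences could be given a whole number of reads. A read was worth 0.027296 to 0.099973 ppm, and libraries held 1783668 to 10620949 antisense 22G reads, which were 13.97% to 37.17% of the deposited total. Because the deposited files hold RPM values and only 1 class of small RNA, the count-model test planned for whole read counts was replaced by limma-trend on log2 values.

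Antisense reads were summed per gene. Libraries were scaled by a trimmed mean of log ratios of antisense reads (30% of log ratios and 5% of mean log values trimmed) and expressed as log2 of RPM plus 1. Genes entered a comparison with at least 10 reads at the median depth in 3 libraries and at least 15 reads in all. The limma model (version 3.58.1, R 4.3.3, robust trend) compared znfx-1 with wild type in each of the 4 kinds of library. It compared IP with input in each genotype and strain, and tested the difference between genotypes of that enrichment, which made 10 comparisons of level. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Levels in the text are group means with SD (n = 3) on the scale of the comparison they belong to, so an input value can differ slightly between comparisons.

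Genes bound by an Argonaute were those with an IP over input log2 fold of at least 1 past the threshold in wild type. Each of these 2 classes was tested only in the input of the other strain, which shares no library with its definition. Fixed before the data were examined were 15 gene lists: argonautes, RdRP and Mutator factors, P granule and perinuclear factors, nuclear RNAi and chromatin factors, oogenesis and maternal genes, meiosis, chromosome segregation, spermatogenesis, histones, ribosomal proteins, collagens, intestine, muscle, neurons, and reference loci of the 26G and WAGO pathways. Of the listed names, 2 argonautes, 1 RdRP or Mutator factor, 1 neuronal gene and 6 reference loci were not found in the files. Lists and classes were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Gene names were matched to the RefSeq annotation table of assembly WBcel235, used only for names and mRNA lengths; 19654 of 20094 names (97.8%) matched.

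Position was the mean place of the 5' base of a gene's 22G-RNAs along its mRNA, from 0 at the 5' end to 1 at the 3' end, with the end taken as the largest such base seen. It was computed for genes with at least 50 antisense reads in every library of a comparison, 4 comparisons in all, and compared with limma. For 3087 genes with that depth in all 24 libraries, the length seen had a median of 1.02 times the annotated mRNA length and was within 10% of it for 78.1%. The mean over genes was compared by a two-sided exact permutation test over the 20 assignments of 3 against 3 libraries, whose smallest possible p is 0.1.

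Genes named in the text follow a rule fixed before the data were examined. Among genes past the threshold whose groups did not overlap and whose higher mean was at least 10 RPM, these were the 5 with the largest fold in each direction, the same again among genes with a genetic name, and from each list up to 3 members with the smallest adjusted p; znfx-1, csr-1 and hrde-1 were always included. For positions these were the 5 largest shifts in each direction and the same lists. Genes named outside this rule are marked as chosen after their values were seen.

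Pairing was checked, since the replicate numbers of the labels could stand for shared preparations: after subtracting group means, the residuals of libraries with the same number were correlated across genes. In the CSR-1 IP r was 0.78, 0.45 and 0.47 between genotypes, but only 2 of 6 libraries matched their own number best. All comparisons were also fitted with this number as a block. IP and input of the same number gave r of 0.16, 0.26 and 0.10 in the wild-type CSR-1 strain and 0.31, 0.47 and 0.18 in the mutant WAGO-9 strain. Comparisons of IP with input were therefore also fitted with a replicate block within each genotype. Between genotypes the inputs of the CSR-1 strain gave 0.19, −0.03 and 0.06, those of the WAGO-9 strain 0.08, −0.12 and −0.01, and the WAGO-9 IPs −0.08, −0.33 and −0.14, so the numbers did not pair these libraries.

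The level test was run on simulated data with 200 changed genes per comparison (the data called 1227 to 6943), too few to test scaling. For 2-fold changes it recovered 75% in the CSR-1 input (9012 genes), 14% in the CSR-1 IP (8762), 78% in the WAGO-9 input (9565) and 82% in the WAGO-9 IP (11418). For 4-fold changes it recovered 95%, 85%, 92% and 98% in the same order, with 4%, 4.8%, 6.1% and 1.6% of calls false. Simulated shifts in position of 0.1 were recovered in 57.6%, 4.5%, 59.1% and 65.2% of genes (4876, 5108, 4955 and 5376 run) and shifts of 0.2 in 84.8%, 56.1%, 95.5% and 92.4%. False calls were 6%, 4.8%, 1.8% and 3.7%.

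Alternatives planned before the data were examined were scaling by totals, no filter, other minimum reads and lengths for positions, distinct positions, the replicate block, sequences listed once, a log2 fold of at least 1, and leaving out each replicate. Added after seeing the data were median-of-ratios scaling, the deposited values without rescaling, limma voom (same version) on the recovered reads, pseudocounts of 0.25 and 5, a replicate block within each genotype or kind of library, and leaving out the CSR-1 IP libraries numbered 1. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Sense and unmapped reads were left out of every comparison.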

Results

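Antisense 22G-RNAs, which RNA-dependent RNA polymerases make on target mRNAs and Argonautes then carry, were measured in whole C. elegans of 2 strains. In 1 strain CSR-1 carried a FLAG tag and in the other WAGO-9, the nuclear Argonaute encoded by hrde-1. CSR-1 carries small RNAs against genes expressed in the germline, and WAGO-9 carries those of heritable silencing. ZNFX-1 is a helicase of perinuclear granules in germ cells. Each strain was sampled as wild type and as znfx-1(ne4354), with 3 libraries of total small RNA (input) and 3 of the Argonaute IP per genotype, 24 libraries in all. The libraries held 1783668 to 10620949 antisense 22G reads. Levels are RPM as mean ± SD (n = 3 in every group), folds and medians are log2, and adjusted p-values come from limma. The scaling sets the typical gene near 0, so changes are relative to other genes.

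The mutated gene itself was read in every library. In znfx-1 mutants, 22G-RNAs against znfx-1 fell from 362 ± 14.6 to 115 ± 9.54 in the input of the CSR-1 strain (log2 −1.65, adjusted p = 6.22e-08). They fell from 393 ± 23.1 to 117 ± 7.14 in the input of the WAGO-9 strain (log2 −1.74, adjusted p = 1.01e-07). In the WAGO-9 IP they fell from 346 ± 3.45 to 26.6 ± 3.902 (log2 −3.66, adjusted p = 6.16e-06). In the CSR-1 IP they fell from 879 ± 152 to 327 ± 94 (log2 −1.45, adjusted p = 0.0273). That last call was lost with scaling by totals (log2 −1.301), with deposited values (log2 −1.245), without wild-type replicate 3 (−1.387) and without mutant replicate 1 (−1.232), 2 (−1.656) or 3 (−1.568). In bases 5001 to 5500 of the znfx-1 mRNA 12 wild-type libraries held 18 to 352 reads and 12 mutant ones 0 to 6. This window was picked from several, so it does not test the labels. A count of 0 allows up to 3 reads, by counting error only.

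Which genes CSR-1 served was asked by comparing its IP with the input. In wild type, 22G-RNAs against the P granule helicase gene glh-2 rose from 52.9 ± 5.14 to 262 ± 39.5 between input and IP. Those against the yolk receptor gene rme-2 rose from 148 ± 11.4 to 651 ± 111, the kinetochore kinase gene bub-1 from 275 ± 29.7 to 1006 ± 285 and the meiotic kinase gene chk-2 from 228 ± 21.7 to 835 ± 347. The collagen gene col-72 fell from 40.8 ± 8.499 to 9.14 ± 1.79 and the neuropeptide-processing gene egl-21 from 284 ± 16.3 to 73.9 ± 23.8. Large rises were those of Y75B8A.18, ztf-9 (10.5 ± 2.03 to 460 ± 267, log2 5.19), aipr-1, Y9D1A.2, H12I19.6, gakh-1, sdz-30 and mtm-1. The SD exceeded the mean in the IP for Y75B8A.18 (1054 ± 1202), aipr-1 (1885 ± 2585), gakh-1 (157 ± 167) and mtm-1 (1942 ± 2575), and it was near the mean for Y9D1A.2 (2274 ± 2034). The call at Y9D1A.2 was lost with no filter (adjusted p = 0.0651) and without wild-type input replicate 1 (0.0642) or IP replicate 2 (0.0712) or 3 (0.0776), and that at H12I19.6 without IP replicate 1 (adjusted p = 0.051). Large falls included Y49F6C.6 (245 ± 39.2 to 7.24 ± 5.33), sbsp-1 (79.4 ± 15.4 to 5.09 ± 3.74) and the neuronal gene rgef-1 (21.3 ± 4.14 to 0.902 ± 1.09).

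Of 10483 genes tested in the CSR-1 strain, 3332 were higher and 2602 lower in the wild-type IP than in the input, and 3167 and 1975 in znfx-1. Median-of-ratios scaling put the median gene at −0.14 and the split at 2830 and 3223 in wild type, and at −0.25 with 2619 and 3085 in znfx-1. Scaling by totals put the wild-type median at 0.15. Of 25 chromosome segregation genes, 23 rose and 0 fell (23 and 0 adjusted over the list alone). Their median was 1.26 (adjusted p = 1.35e-07, and adjusted p = 0.376 with an estimated correlation). Among them icp-1 rose from 276 ± 52.2 to 1101 ± 266 and hcp-4 from 185 ± 19.4 to 691 ± 187. Of 21 P granule and perinuclear factors, 17 rose and 0 fell (18 and 0 adjusted over the list alone). Their median was 1.39 (adjusted p = 1.22e-05, and adjusted p = 0.343 with an estimated correlation), and meg-1 rose from 9.55 ± 2.85 to 91.4 ± 32.98. Of 27 oogenesis and maternal genes, 19 rose and 0 fell (21 and 0 adjusted over the list alone). Their median was 1.15 (adjusted p = 1.22e-05, and adjusted p = 0.376 with an estimated correlation), and puf-11 rose by 1.93 and egg-1 by 2.23. Of 24 meiosis genes, 20 rose and 0 fell (20 and 0 adjusted over the list alone). Their median was 0.97 (adjusted p = 4.65e-05, and adjusted p = 0.376 with an estimated correlation). Of 16 nuclear RNAi and chromatin factors, 10 rose and 0 fell (10 and 0 adjusted over the list alone). Their median was 0.95 (adjusted p = 0.00392, and adjusted p = 0.376 with an estimated correlation), and mes-6 rose by 1.88. Of 20 argonaute genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone). Their median was 0.86 (adjusted p = 0.00428, and adjusted p = 0.376 with an estimated correlation), and nrde-3 rose from 11.98 ± 0.751 to 72.5 ± 19.5. 22G-RNAs against csr-1 itself rose from 333 ± 50.3 to 639 ± 304 (log2 0.85, adjusted p = 0.026). This call was lost with median-of-ratios scaling (log2 0.656, adjusted p = 0.0706), with sequences listed once (log2 0.15), without wild-type IP replicate 1 (log2 0.35) and without wild-type input replicate 2 (log2 0.72).

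Other lists fell or went both ways in the wild-type CSR-1 IP. Of 26 collagens, 0 rose and 15 fell (0 and 15 adjusted over the list alone). Their median was −0.98 (adjusted p = 4.05e-05, and adjusted p = 0.343 with an estimated correlation). Of 12 neuronal genes, 0 rose and 6 fell (0 and 8 adjusted over the list alone). Their median was −0.83 (adjusted p = 0.00428, and adjusted p = 0.343 with an estimated correlation). Of 55 histones, 0 rose and 12 fell (0 and 5 adjusted over the list alone). Their median was −0.36 (adjusted p = 0.0185, and adjusted p = 0.491 with an estimated correlation), and the linker histone gene his-24 fell from 2494 ± 339.7 to 746 ± 64.1. Of 19 RdRP and Mutator factors, 9 rose and 4 fell (10 and 4 adjusted over the list alone), with a median of 0.503 (adjusted p = 0.208), with the RdRP gene rrf-3 rising from 91.6 ± 13.4 to 246 ± 43.3. Reference loci included the WAGO target bath-45, which fell from 7879 ± 514 to 2835 ± 691. In znfx-1, glh-2 rose from 36.5 ± 2.49 to 303 ± 23.8 between input and IP, rme-2 from 91.8 ± 7.48 to 639 ± 51.04, the Argonaute gene wago-4 from 413 ± 12.3 to 1781 ± 363 and csr-1 from 207 ± 12.4 to 799 ± 184. Segregation genes there had a median of 1.86 (adjusted p = 3.94e-11, and adjusted p = 0.287 with an estimated correlation). For P granule factors it was 1.903 (adjusted p = 2.05e-07, and adjusted p = 0.287 with an estimated correlation). A direct test of the change in enrichment between genotypes called 5 genes, with 670 under an unadjusted p of 0.05, and limma voom also called 5. Chosen after their values were seen, these were Y54F10AM.11 (higher in znfx-1) and pkn-1, K03A11.1, atg-2 and epg-2 (lower). This count was 0 without any 1 of the 6 input libraries or without mutant IP replicate 2. It was 1 or 2 without wild-type IP replicate 2 or 3 or mutant IP replicate 1 or 3, and 19 without wild-type IP replicate 1. With the replicate number as a block it was 1, and 0 with such a block within each genotype (655 under an unadjusted p of 0.05).

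WAGO-9 carried 22G-RNAs against another set of genes. In wild type, those against the heterochromatin gene hpl-1 rose from 32.7 ± 4.27 to 237 ± 15.1 between input and IP, against his-24 from 1702 ± 242 to 5137 ± 299 and against the synaptic gene unc-10 from 943 ± 95.2 to 3819 ± 428. The 26G target C44B11.6 fell from 7632 ± 382 to 67.4 ± 24.9 (log2 −6.88, adjusted p = 1.74e-09), Y47H10A.5 from 10320 ± 221 to 101 ± 43.9 and the RNAi gene eri-12 from 1185 ± 99.96 to 11.7 ± 2.802. The Argonaute gene sago-1 fell from 338 ± 125 to 5.72 ± 1.217. Further large falls were those of Y36E3A.2 (1461 ± 9.31 to 9.43 ± 4.51), fbxa-52, H09G03.1 and K02E2.6 (4400 ± 76.3 to 66.2 ± 25.4). Large rises were those of Y64G10A.5 (17.99 ± 31.2 to 93.7 ± 45.4), the chemoreceptor gene srz-5 (15.8 ± 3.98 to 294 ± 48.4), pqn-84 (3.55 ± 1.31 to 73.4 ± 14.8), F36H12.9, the phosphatase gene ptp-5.1, scrm-7 and the ribosomal gene rpl-42 (11.97 ± 1.18 to 173 ± 31.7). The call at Y64G10A.5 was lost with limma voom (adjusted p = 0.0622) and without wild-type input replicate 1 (0.085) or 3 (0.0864) or IP replicate 1 (0.0518) or 2 (0.0698).

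Of 12132 genes tested in the WAGO-9 strain, 4328 were higher and 4401 lower in the wild-type IP, and 4154 and 4644 in znfx-1. Scaling by totals put the median gene at −0.32 and the wild-type split at 3082 and 5444. Deposited values put it at 0.27 with 5088 and 2940, and at 0.53 in znfx-1 with 6580 and 2546. With limma voom the wild-type split was 3454 and 4203. Of 70 histones, 33 rose and 3 fell (29 and 2 adjusted over the list alone). Their median was 1 (adjusted p = 0.0016, and adjusted p = 0.421 with an estimated correlation), and his-37 rose from 58.7 ± 10.3 to 270.3 ± 19.2. Of 70 spermatogenesis genes, 42 rose and 8 fell (42 and 8 adjusted over the list alone). Their median was 0.97 (adjusted p = 0.0027, and adjusted p = 0.404 with an estimated correlation), and nspd-1 rose from 1.47 ± 1.01 to 22.3 ± 5.32. Of 24 meiosis genes, 0 rose and 22 fell (0 and 22 adjusted over the list alone). Their median was −1.43 (adjusted p = 5.6e-06, and adjusted p = 0.195 with an estimated correlation), and the synaptonemal gene syp-1 fell with a log2 fold of −2.201. Of 19 RdRP and Mutator factors, 2 rose and 15 fell (2 and 15 adjusted over the list alone). Their median was −1.06 (adjusted p = 0.0016, and adjusted p = 0.281 with an estimated correlation), and the RdRP gene ego-1 fell from 141 ± 8.35 to 51.3 ± 3.221. Of 27 oogenesis and maternal genes, 3 rose and 20 fell (3 and 20 adjusted over the list alone). Their median was −1.02 (adjusted p = 0.0016, and adjusted p = 0.281 with an estimated correlation), yet puf-5 rose from 116 ± 10.1 to 389 ± 22.2. Of 21 P granule factors, 1 rose and 13 fell (1 and 13 adjusted over the list alone). Their median was −0.99 (adjusted p = 0.00728, and adjusted p = 0.404 with an estimated correlation), and pgl-1 fell from 279 ± 32.5 to 84.7 ± 2.68.

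Ribosomal protein genes were mostly lower in the wild-type WAGO-9 IP. Of 75 ribosomal protein genes, 4 rose and 48 fell (4 and 48 adjusted over the list alone). Their median was −0.94 (adjusted p = 0.0016, and adjusted p = 0.463 with an estimated correlation). The rise of rps-26 from 20.4 ± 4.05 to 119 ± 2.86 turned to a log2 of −0.17 with sequences listed once. Of 25 segregation genes, 5 rose and 18 fell (5 and 18 adjusted over the list alone). Their median was −0.9 (adjusted p = 0.00669, and adjusted p = 0.404 with an estimated correlation), yet smc-4 rose from 124 ± 9.01 to 431 ± 38.6. Of 16 nuclear RNAi factors, 2 rose and 11 fell (2 and 11 adjusted over the list alone). Their median was −0.77 (adjusted p = 0.033, and adjusted p = 0.404 with an estimated correlation). Of 11 reference loci, 3 rose and 6 fell (3 and 6 adjusted over the list alone). Their median was −2.85 (adjusted p = 0.033, and adjusted p = 0.404 with an estimated correlation). Of 46 collagens, 16 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.598 (adjusted p = 0.085). hrde-1 itself rose from 595 ± 71.8 to 994 ± 11.04 (log2 0.75, adjusted p = 0.000273), a call lost with scaling by totals (log2 0.29, adjusted p = 0.115). csr-1 fell from 273 ± 12.3 to 130.4 ± 4.29 (log2 −1.06). In znfx-1, C44B11.6 fell from 3483 ± 263 to 24.1 ± 7.1 between input and IP and Y36E3A.2 from 1278 ± 48.9 to 4.17 ± 1.67. There his-24 rose from 1068 ± 99.2 to 3322 ± 515 and unc-10 from 942 ± 240.1 to 3007 ± 1078, and wago-4 fell from 262 ± 48.5 to 43.6 ± 5.74. hrde-1 went from 293 ± 7.76 to 279.6 ± 50.2 and was not called (adjusted p = 0.597). Of 9 intestinal genes in znfx-1, 1 rose and 8 fell (1 and 8 adjusted over the list alone). Their median was −2.53 (adjusted p = 0.0282, and adjusted p = 0.419 with an estimated correlation).

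CSR-1 bound 2439 of 10483 genes in wild type and WAGO-9 3116 of 12132. Among the 10207 genes tested in both strains, 2398 were bound by CSR-1 and 2263 by WAGO-9, and 199 were in both classes (531.7 by chance). In znfx-1 these numbers were 2459 and 2069, with 203 in both (498.4 by chance). Between genotypes, 2004 CSR-1-bound genes (579.1 by chance) and 2313 WAGO-9-bound genes (750.5 by chance) were bound in both. Wild-type classes were chosen for enrichment in the wild-type IP of their own strain, so their shares of reads were compared between genotypes in the input of the other strain. CSR-1-bound genes held a mean of 9.33% of the input of the WAGO-9 strain in wild type and 7.55% in znfx-1. WAGO-9-bound genes held 23.46% and 25.24% of the input of the CSR-1 strain. Within the input of their own strain, which took part in choosing the class, they went the other way, from 19.51% to 16.83%, and CSR-1-bound genes from 10.19% to 8.12%. The share of CSR-1-bound genes in the wild-type CSR-1 IP ranged from 28.28% to 47.86% between replicates, with 95% Wilson intervals no wider than 0.14 points.

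**Figure D1:**
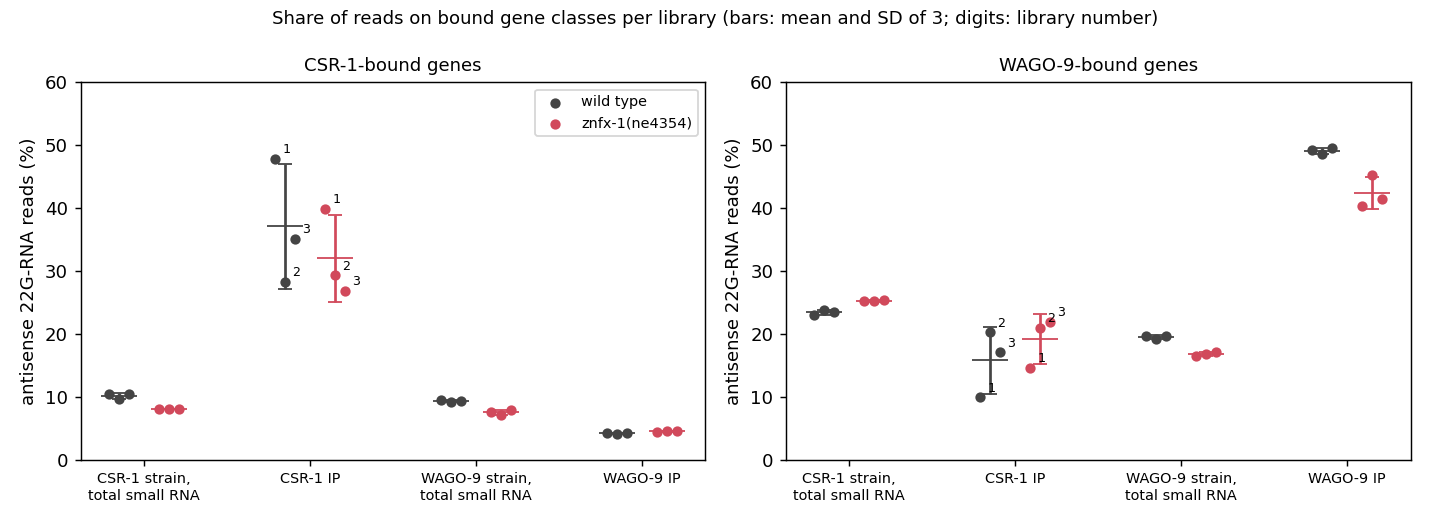
Percent of antisense 22G reads against CSR-1-bound and WAGO-9-bound genes in each library. The classes were chosen in the wild-type IP of their own strain, so a lower share in its mutant IP is partly built in. In the input of the CSR-1 strain WAGO-9-bound genes hold 23.46% in wild type and 25.24% in znfx-1, and in that of the WAGO-9 strain 19.51% and 16.83%.

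Total small RNA of the CSR-1 strain was compared between znfx-1 and wild type to ask which targets lose or gain 22G-RNAs without ZNFX-1. Small RNAs against hrde-1 fell from 675 ± 20.04 to 381 ± 9.15, the piRNA Argonaute gene prg-1 from 597 ± 41.95 to 361 ± 20.9 and the RNAi gene rde-11 from 1894 ± 349 to 423 ± 37.3. glh-1 fell from 299.8 ± 17.8 to 127 ± 3.18 and the nuclear RNAi gene nrde-2 from 524 ± 38.6 to 261 ± 11.2. Large gains were seen at the talin gene tln-1, from 53.02 ± 8.34 to 1332 ± 55.04 (log2 4.64), and the chemoreceptor gene str-264, from 3.01 ± 1.54 to 155 ± 21.2. Large losses were seen at B0261.8 (969 ± 58.9 to 22.3 ± 4.01), the transcription factor gene hlh-11 (344 ± 70.7 to 7.34 ± 1.44, log2 −5.37), gtf-2A2 (775 ± 143 to 19.1 ± 3.53) and zip-7. The calponin-like gene cpn-4 fell from 1657 ± 57.2 to 64.8 ± 5.92. F14E5.8 (2.38 ± 1.48 to 313 ± 31.3), K09E4.4, C51E3.9, R03D7.2 (46.5 ± 3.16 to 1695 ± 66.2), lgc-45, ist-1 and eva-1 also rose, and T16H12.2 and pugs-4 fell.

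Of 9910 genes tested in that input, 2739 rose and 3175 fell, 1890 and 568 of them by a log2 of at least 1, and limma voom gave 2736 and 3206. Deposited values moved the median gene from −0.12 to 0.008 and the split to 2918 and 1908. Of 19 RdRP and Mutator factors, 1 rose and 15 fell (1 and 16 adjusted over the list alone). Their median was −0.55 (adjusted p = 0.00127, and adjusted p = 0.127 with an estimated correlation). The RdRP gene rrf-1 fell from 206 ± 10 to 115 ± 6.52 and rrf-2 rose from 303 ± 40.4 to 686 ± 18.4. Of 16 nuclear RNAi and chromatin factors, 0 rose and 15 fell (0 and 15 adjusted over the list alone). Their median was −0.55 (adjusted p = 5e-04, and adjusted p = 0.127 with an estimated correlation). The histone methyltransferase gene set-2 fell from 282 ± 6.77 to 141 ± 4.69 and met-2 from 185 ± 11.7 to 93.8 ± 0.536. Of 21 P granule and perinuclear factors, 1 rose and 14 fell (1 and 14 adjusted over the list alone). Their median was −0.47 (adjusted p = 0.0063, and adjusted p = 0.14 with an estimated correlation). Of 17 argonaute genes, 4 rose and 9 fell (4 and 9 adjusted over the list alone), with a median of −0.43 (adjusted p = 0.293), and wago-11 rose from 0.974 ± 0.402 to 10.3 ± 0.878. csr-1 fell from 302 ± 41.01 to 213 ± 10.2 (log2 −0.49, adjusted p = 0.00297), a call lost with deposited values (adjusted p = 0.0673).

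Germline and ribosomal lists of the same input were compared too. Of 25 segregation genes, 1 rose and 20 fell (1 and 20 adjusted over the list alone). Their median was −0.49 (adjusted p = 0.00043, and adjusted p = 0.27 with an estimated correlation). Among them spd-5 fell from 198 ± 13.8 to 112 ± 2.81 and air-2 from 128 ± 8.56 to 74.3 ± 2.25. Of 24 meiosis genes, 0 rose and 14 fell (0 and 14 adjusted over the list alone). Their median was −0.49 (adjusted p = 0.00127, and adjusted p = 0.228 with an estimated correlation), and chk-2 fell from 206 ± 14.7 to 110.1 ± 9.16. Of 27 oogenesis and maternal genes, 1 rose and 11 fell (1 and 8 adjusted over the list alone). Their median was −0.34 (adjusted p = 0.0362, and adjusted p = 0.469 with an estimated correlation), with gld-1 falling from 89.1 ± 16.3 to 51.3 ± 6.59 and nos-2 rising from 26.9 ± 3.88 to 68.7 ± 6.66. Of 15 spermatogenesis genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone), with a median of 0.02 (adjusted p = 0.693). The sperm genes spe-18 (0.648 ± 0.442 to 22.8 ± 3.401) and spe-9 (2.79 ± 1.46 to 41.5 ± 6.23) rose. Of 45 histones, 8 rose and 7 fell (8 and 6 adjusted over the list alone), with a median of 0.08 (adjusted p = 0.596), with his-74 falling from 49.1 ± 6.39 to 21.8 ± 3.73. Of 73 ribosomal protein genes, 3 rose and 19 fell (3 and 15 adjusted over the list alone), with a median of −0.33 (adjusted p = 0.0528), and rpl-11.2 rose from 10.3 ± 2.49 to 44.3 ± 6.797.

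Somatic lists and reference loci of this input were compared too. Of 25 collagens, 14 rose and 3 fell (14 and 3 adjusted over the list alone). Their median was 0.82 (adjusted p = 0.00758, and adjusted p = 0.228 with an estimated correlation). col-68 rose from 1.61 ± 0.572 to 57.1 ± 3.55 and col-38 fell from 96.3 ± 11.5 to 14.2 ± 2.903. Of 12 neuronal genes, 7 rose and 3 fell (7 and 4 adjusted over the list alone), with a median of 1.26 (adjusted p = 0.0525), with unc-31 rising from 20.8 ± 1.27 to 138 ± 11.8 and unc-10 from 565 ± 49.3 to 1649 ± 55.7. Of 5 muscle genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.76 (adjusted p = 0.0572), and the titin gene ttn-1 rose from 6.14 ± 1.75 to 21.1 ± 2.15. Of 9 intestinal genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone), with a median of −1.27 (adjusted p = 0.0614), and the vitellogenin gene vit-3 fell from 8.56 ± 4.03 to 1.53 ± 1.14. Of 11 reference loci, 2 rose and 6 fell (2 and 6 adjusted over the list alone), with a median of −0.49 (adjusted p = 0.0619). The 26G target E01G4.5 fell from 5173 ± 633 to 810.4 ± 25.7 (log2 −2.67, adjusted p = 1.09e-09) and the sex determination gene xol-1 from 394 ± 72.4 to 79.5 ± 0.825.

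Total small RNA of the WAGO-9 strain answered the same question in the other strain. There hrde-1 fell from 647 ± 76.6 to 317 ± 5.24, nrde-2 from 692 ± 50.5 to 266 ± 11.61, rde-11 from 1357 ± 146 to 529 ± 34.2 and the Vasa-like gene glh-4 from 417 ± 12.6 to 228 ± 17.1. tln-1 rose from 27.8 ± 3.16 to 2301 ± 176 (log2 6.33) and the kinase gene cdk-14 from 20.1 ± 1.21 to 2090 ± 304 (log2 6.62). The touch channel gene trp-4 rose from 13.2 ± 0.594 to 804 ± 128 and the sperm genes spe-18 from 0.686 ± 0.493 to 158 ± 36.5 and spe-15 from 22.9 ± 3.88 to 526 ± 54.01. Large losses were those of the F-box gene fbxa-61 (174 ± 11.9 to 4.23 ± 1.58, log2 −5.104), gtf-2A2 (494 ± 68.1 to 27.5 ± 10.3), hlh-11 (204 ± 9.81 to 17.2 ± 5.197), nhr-1, M01A10.4, R03G8.2 and clec-166. C39F7.1 (1.703 ± 1.16 to 241 ± 34.5), F14E5.8 and nas-30 were further large gains.

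In this input 2572 of 10292 genes rose and 2752 fell, 1702 and 682 by a log2 of at least 1, and limma voom gave 2472 and 2773. Deposited values put the median gene at 0.28 and the split at 4031 and 785. Of 16 nuclear RNAi and chromatin factors, 0 rose and 10 fell (0 and 10 adjusted over the list alone). Their median was −0.43 (adjusted p = 0.00111, and adjusted p = 0.219 with an estimated correlation). That median turned to 0.014 with deposited values. Of 19 RdRP and Mutator factors, 1 rose and 13 fell (1 and 13 adjusted over the list alone). Their median was −0.501 (adjusted p = 0.00354, and adjusted p = 0.219 with an estimated correlation), and rrf-2 rose from 171 ± 15.4 to 335 ± 65.7. Of 21 P granule and perinuclear factors, 1 rose and 14 fell (1 and 14 adjusted over the list alone). Their median was −0.66 (adjusted p = 0.00831, and adjusted p = 0.406 with an estimated correlation), yet meg-4 rose from 6.91 ± 1.04 to 26.7 ± 3.34. Of 18 argonaute genes, 5 rose and 7 fell (5 and 7 adjusted over the list alone), with a median of −0.34 (adjusted p = 0.464). Their mean was 0.14, opposite in sign to the median, which turned to 0.098 with deposited values. vsra-1 rose from 8.53 ± 1.36 to 56.98 ± 4.91 and wago-11 from 2.12 ± 0.742 to 12.3 ± 1.44. csr-1 fell from 297 ± 12.18 to 171 ± 19.4 (log2 −0.799, adjusted p = 0.000131), which deposited values did not call (adjusted p = 0.0971).

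Germline and somatic lists of the WAGO-9 strain were compared too. Of 25 segregation genes, 0 rose and 20 fell (0 and 22 adjusted over the list alone). Their median was −0.58 (adjusted p = 1.5e-05, and adjusted p = 0.162 with an estimated correlation), and bub-1 fell from 241 ± 3.799 to 132 ± 5.26. Of 24 meiosis genes, 1 rose and 14 fell (1 and 14 adjusted over the list alone). Their median was −0.51 (adjusted p = 0.00111, and adjusted p = 0.219 with an estimated correlation), and hal-2 fell from 234.7 ± 9.12 to 97.99 ± 12.1. Of 27 oogenesis and maternal genes, 0 rose and 14 fell (0 and 14 adjusted over the list alone). Their median was −0.39 (adjusted p = 0.0018, and adjusted p = 0.368 with an estimated correlation), or 0.035 with deposited values, and gld-1 fell from 94.2 ± 9.197 to 49.3 ± 10.02. Of 44 spermatogenesis genes, 10 rose and 5 fell (10 and 5 adjusted over the list alone). Their median was 0.41 (adjusted p = 0.0462, and adjusted p = 0.287 with an estimated correlation). Of 56 histones, 1 rose and 9 fell (0 and 6 adjusted over the list alone), with a median of −0.397 (adjusted p = 0.0538), and his-4 fell from 31.7 ± 1.15 to 16.1 ± 0.6. Of 74 ribosomal protein genes, 6 rose and 1 fell (1 and 0 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.22). Of 30 collagens, 17 rose and 3 fell (17 and 3 adjusted over the list alone). Their median was 1.09 (adjusted p = 0.00111, and adjusted p = 0.219 with an estimated correlation), with col-68 rising from 2.28 ± 0.622 to 74.1 ± 5.48. Of 11 neuronal genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.64), with unc-31 rising from 4.09 ± 1.36 to 44.3 ± 3.25 and rab-3 falling from 72.8 ± 7.79 to 15.95 ± 5.56. Of 3 muscle genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.75 (adjusted p = 0.206). Of 7 intestinal genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.66 (adjusted p = 0.317). Of 11 reference loci, 0 rose and 7 fell (0 and 7 adjusted over the list alone). Their median was −1.03 (adjusted p = 0.00145, and adjusted p = 0.162 with an estimated correlation), with bath-45 falling from 3945 ± 41.1 to 1511 ± 138 and C44B11.6 from 8311 ± 440.3 to 3769 ± 252.

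Between the 2 inputs, 9347 genes were tested in both. Of these, 1424 rose in both strains (556.3 by chance) and 1728 fell in both (898.3 by chance), while 418 went opposite ways. Across genes, which are not independent replicates, the folds correlated with Pearson's r of 0.59 and Spearman's rho of 0.55.

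**Figure D2:**
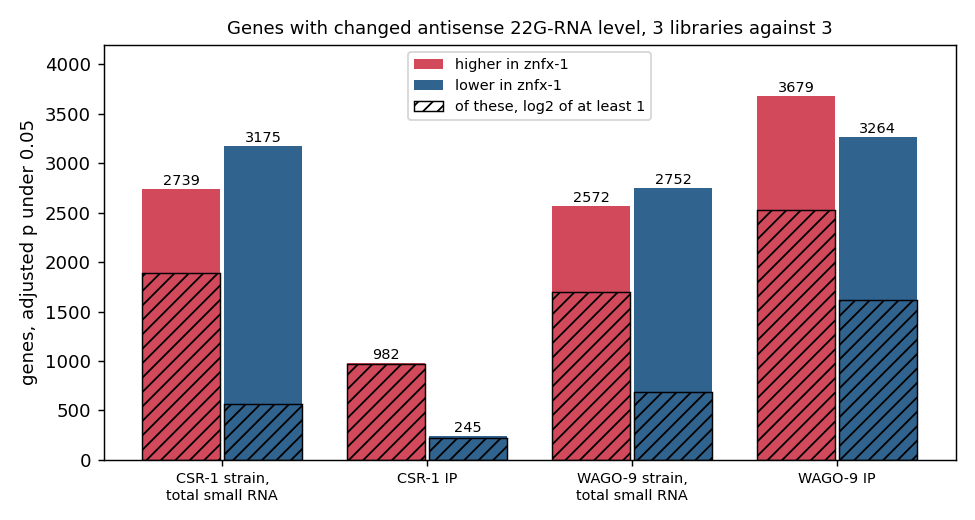
Number of genes with higher and lower antisense 22G-RNA level in znfx-1 than in wild type for each kind of library (limma, adjusted p threshold 0.05). The WAGO-9 IP has 3679 higher and 3264 lower, and the CSR-1 IP 982 and 245.

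CSR-1-bound and WAGO-9-bound genes were each followed in the input of the strain that did not define them. In the input of the CSR-1 strain, 1108 of 2080 WAGO-9-bound genes rose and 414 fell, with a median of 0.67 against −0.205 for other genes. This difference had p = 6.64e-11 with limma's camera, and p = 0.00412 with an estimated correlation. In the input of the WAGO-9 strain, 223 of 2287 CSR-1-bound genes rose and 872 fell, with a median of −0.29 against 0.04. It had p = 1.68e-06, and p = 0.102 with an estimated correlation, and with deposited values the median turned to 0.11, below the 0.28 of all genes.

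22G-RNAs in the CSR-1 IP were compared to ask whether the cargo of CSR-1 depends on ZNFX-1. E01G4.5 fell from 9418 ± 4182 to 1070 ± 306 (log2 −3.08, adjusted p = 0.00549), hlh-11 from 233 ± 108 to 9.48 ± 6.84 and cpn-4 from 565 ± 175 to 46.8 ± 6.47. The cadherin gene cdh-5 rose from 6.21 ± 1.29 to 227 ± 21.2, spe-9 from 1.98 ± 0.809 to 24.1 ± 6.03, the histone gene his-18 from 2.21 ± 0.802 to 31.7 ± 16.9 and col-68 from 0.9602 ± 0.319 to 27.6 ± 8.51. csr-1 was 658 ± 338 in wild type and 835 ± 188 in znfx-1, and hrde-1 2157 ± 2572 and 1468 ± 1374, neither of them called (adjusted p = 0.522 and 0.886). Large gains were also seen at F14E5.8 (3.87 ± 3.24 to 329 ± 164), K08E7.5, C51E3.9, T22F7.3, K09E4.4 (4.25 ± 0.6397 to 209.9 ± 14.2), eva-1, lgc-45, ist-1 and fmil-1. F40H3.6 (1243 ± 521 to 52.4 ± 10.5), B0261.8 (465 ± 252 to 18.4 ± 3.101), Y13C8A.2, zip-7 and madf-9 lost 22G-RNAs.

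In the CSR-1 IP 982 of 9430 genes rose and 245 fell, 973 and 220 by a log2 of at least 1, and limma voom gave 931 and 238. With the replicate number as a block 3680 genes were called, 1897 higher and 1783 lower. Without wild-type replicate 3 the count was 433, without mutant replicate 2 it was also 433, and without mutant replicate 3 it was 336. The median gene was −0.18, and −0.035 with totals and 0.004 with deposited values. Of 2435 CSR-1-bound genes, a class chosen with the wild-type libraries of this IP, 23 rose and 40 fell. Among the 6995 other genes 959 rose and 205 fell. Most calls therefore lay outside the genes that CSR-1 bound in wild type and do not by themselves show a change in its cargo. The call at hlh-11 was lost with the block (adjusted p = 0.0627). rde-11 fell from 869 ± 418 to 224 ± 46.6 and xol-1 from 287 ± 152 to 67.2 ± 11.5, but the call at rde-11 was lost without wild-type replicate 2 (adjusted p = 0.0696) or 3 (0.143) or mutant replicate 1 (0.0786), 2 (0.112) or 3 (0.114). That at xol-1 was lost without wild-type replicate 3 (adjusted p = 0.105) or mutant replicate 1 (0.0582), 2 (0.0851) or 3 (0.0944), and both were lost with totals (adjusted p = 0.0824 and 0.0561) and deposited values (0.146 and 0.099). Without wild-type replicate 3 (adjusted p = 0.0683) or mutant replicate 3 (0.0546) the call at Y13C8A.2 was lost.

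Lists in the CSR-1 IP went both ways. Of 19 collagens, 6 rose and 1 fell (9 and 1 adjusted over the list alone). Their median was 0.98 (adjusted p = 0.0012, and adjusted p = 0.675 with an estimated correlation), with col-38 falling from 64.4 ± 12.6 to 10.4 ± 0.525. Of 11 neuronal genes, 5 rose and 0 fell (7 and 2 adjusted over the list alone). Their median was 1.197 (adjusted p = 0.0345, and adjusted p = 0.675 with an estimated correlation), with egl-3 rising from 0.513 ± 0.0991 to 6.64 ± 0.558 and unc-104 from 9.996 ± 0.624 to 38.9 ± 9.48. Of 6 muscle genes, 1 rose and 0 fell (4 and 0 adjusted over the list alone). Their median was 1.08 (adjusted p = 0.04, and adjusted p = 0.675 with an estimated correlation), and unc-89 rose from 1.57 ± 0.335 to 7.85 ± 2.12. Of 38 histones, 6 rose and 0 fell (7 and 0 adjusted over the list alone). Their median was 0.28 (adjusted p = 0.0482, and adjusted p = 0.675 with an estimated correlation), and his-28 rose by 2.57. Of 24 meiosis genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). Their median was −0.38 (adjusted p = 0.0345, and adjusted p = 0.799 with an estimated correlation). Of 16 nuclear RNAi factors, 0 rose and 0 fell (0 and 0 adjusted over the list alone). Their median was −0.41 (adjusted p = 0.04, and adjusted p = 0.675 with an estimated correlation). Of 77 ribosomal protein genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone). Their median was −0.49 (adjusted p = 0.0345, and adjusted p = 0.931 with an estimated correlation), and rpl-11.2 rose from 3.596 ± 0.533 to 17.5 ± 6.54. Of 14 spermatogenesis genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.238), and spe-15 rose from 12.7 ± 3.46 to 38.7 ± 4.59. Without wild-type replicate 3 the calls at unc-89 (adjusted p = 0.0654), unc-104 (0.0518) and spe-15 (0.0786) were lost. Without mutant replicate 2 those at unc-89 (adjusted p = 0.0738), his-28 (0.0576), spe-15 (0.0706) and rpl-11.2 (0.0513) were lost, and without mutant replicate 3 those at unc-89 (adjusted p = 0.0515), unc-104 (0.0686), his-28 (0.0761) and spe-15 (0.0934).

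The remaining lists of the CSR-1 IP were not called in the fit without the replicate block. Of 19 RdRP and Mutator factors, 0 rose and 1 fell (0 and 0 adjusted over the list alone), with a median of −0.38 (adjusted p = 0.0853). Of 11 reference loci, 0 rose and 2 fell (0 and 2 adjusted over the list alone), with a median of −0.26 (adjusted p = 0.255). Of 21 P granule factors, 0 rose and 2 fell (0 and 2 adjusted over the list alone), with a median of −0.13 (adjusted p = 0.238), a median that was 0.017 with totals and 0.055 with deposited values. Of 18 argonaute genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of −0.06 (adjusted p = 0.948). Their mean was 0.055 and their median 0.087 with totals and 0.119 with deposited values, and wago-11 rose from 1.67 ± 0.927 to 8.08 ± 2.19. Its call was lost without wild-type replicate 3 (adjusted p = 0.0864) or mutant replicate 2 (0.0703) or 3 (0.0884). Of 25 segregation genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of −0.22 (adjusted p = 0.511). Of 27 oogenesis and maternal genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of −0.03 (adjusted p = 0.948), a median that was 0.12 with totals and 0.16 with deposited values. Of 4 intestinal genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of −0.16 (adjusted p = 0.948). Of the genes called in both the IP and its input, 945 rose in both (243.6 by chance), 219 fell in both (81.7 by chance) and 0 went opposite ways.

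22G-RNAs in the WAGO-9 IP were compared to ask the same of WAGO-9. Small RNAs against nrde-2 fell from 609.9 ± 46.2 to 115 ± 9.74, wago-4 from 194 ± 7.97 to 41.4 ± 5.48, csr-1 from 116 ± 4.34 to 37.97 ± 6.19 and glh-4 from 195 ± 17.6 to 28.7 ± 2.38. Those against hrde-1 itself fell from 888 ± 12.9 to 266 ± 48.2 (log2 −1.75, adjusted p = 0.000126). tln-1 rose from 29.5 ± 4.28 to 4357 ± 767 (log2 7.15), trp-4 from 4.13 ± 0.643 to 423 ± 166, the synaptic gene elks-1 from 9.495 ± 1.71 to 826 ± 282 and spe-15 from 13.96 ± 0.8204 to 252 ± 8.95. Large losses included hlh-11 (482 ± 43.7 to 17.3 ± 2.38, log2 −4.73), gtf-2A2, the homeobox gene irx-1 (250 ± 12.8 to 13.3 ± 2.69), srz-5 (263 ± 46.4 to 16.9 ± 12.04), M01A10.4, F22B3.3, C46F11.6 and msra-1. cdk-14, R10F2.6 and lgc-45 (0.564 ± 0.0863 to 86.3 ± 25.4) were further gains.

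In the WAGO-9 IP 3679 of 12245 genes rose and 3264 fell, 2524 and 1612 by a log2 of at least 1, and limma voom gave 3318 and 3252. Totals moved the median gene from 0.07 to 0.44 and the split to 5196 and 1885, and deposited values to 0.52 with 6216 and 1277. Of 25 segregation genes, 0 rose and 20 fell (0 and 21 adjusted over the list alone). Their median was −1.19 (adjusted p = 3.96e-07, and adjusted p = 0.348 with an estimated correlation), and icp-1 fell from 207 ± 8.395 to 52.4 ± 3.47. Of 27 oogenesis and maternal genes, 1 rose and 18 fell (1 and 19 adjusted over the list alone). Their median was −0.72 (adjusted p = 0.000139, and adjusted p = 0.348 with an estimated correlation), and puf-5 fell from 347 ± 22.1 to 63.04 ± 9.05. Of 16 nuclear RNAi and chromatin factors, 0 rose and 12 fell (0 and 12 adjusted over the list alone). Their median was −0.74 (adjusted p = 0.000131, and adjusted p = 0.348 with an estimated correlation), and met-2 fell from 108 ± 8.201 to 21.6 ± 0.252. Of 21 P granule and perinuclear factors, 4 rose and 13 fell (4 and 14 adjusted over the list alone). Their median was −0.88 (adjusted p = 0.0176, and adjusted p = 0.348 with an estimated correlation), yet meg-4 rose from 7.097 ± 0.317 to 45.6 ± 3.76. Of 19 RdRP and Mutator factors, 3 rose and 12 fell (4 and 12 adjusted over the list alone). Their median was −0.91 (adjusted p = 0.0288, and adjusted p = 0.36 with an estimated correlation), and ego-1 fell from 45.8 ± 2.76 to 15.9 ± 1.08. Of 24 meiosis genes, 3 rose and 11 fell (3 and 11 adjusted over the list alone). Their median was −0.37 (adjusted p = 0.0288, and adjusted p = 0.36 with an estimated correlation), or 0.037 with totals and 0.23 with deposited values, and htp-1 fell from 133 ± 12.8 to 24.4 ± 4.37.

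Further lists of the WAGO-9 IP were compared too. Of 70 histones, 2 rose and 28 fell (0 and 24 adjusted over the list alone). Their median was −0.49 (adjusted p = 0.0045, and adjusted p = 0.358 with an estimated correlation), or 0.039 with deposited values, and his-54 fell from 114 ± 7.97 to 29.1 ± 7.01. Of 42 collagens, 19 rose and 5 fell (19 and 5 adjusted over the list alone). Their median was 0.58 (adjusted p = 0.0288, and adjusted p = 0.348 with an estimated correlation), and col-158 rose from 1.497 ± 0.1199 to 22.9 ± 3.63. Of 20 argonaute genes, 4 rose and 8 fell (4 and 8 adjusted over the list alone), with a median of −0.46 (adjusted p = 0.4). Their mean was 0.07, opposite in sign to the median, which was 0.15 with deposited values, and vsra-1 rose from 3.96 ± 0.804 to 45.5 ± 5.03. Of 74 spermatogenesis genes, 19 rose and 6 fell (16 and 4 adjusted over the list alone), with a median of 0.31 (adjusted p = 0.131), and spe-9 rose from 1.07 ± 0.228 to 30.6 ± 5.51. Of 74 ribosomal protein genes, 15 rose and 7 fell (14 and 5 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.338). Of 13 neuronal genes, 6 rose and 3 fell (6 and 3 adjusted over the list alone), with a median of 0.56 (adjusted p = 0.708), with unc-31 rising from 0.0679 ± 0.118 to 19.99 ± 4.71 and rab-3 falling from 128 ± 6.56 to 21.8 ± 3.47. Of 5 muscle genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.67 (adjusted p = 0.185). Of 2 intestinal genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.746). Of 11 reference loci, 1 rose and 6 fell (1 and 6 adjusted over the list alone). Their median was −0.84 (adjusted p = 0.0288, and adjusted p = 0.382 with an estimated correlation), with bath-45 falling from 3991 ± 109.9 to 1981 ± 267, a call lost with deposited values (log2 −0.33, adjusted p = 0.102). Of genes called in both the IP and its input, 2063 rose in both (733.3 by chance), 2165 fell in both (816.9 by chance) and 50 went opposite ways.

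Whether ZNFX-1 sets where along an mRNA 22G-RNAs are made was asked from their positions, with 0 at the 5' end and 1 at the 3' end. On the dystrophin gene dys-1 the mean position moved in znfx-1 from 0.908 ± 0.012 to 0.193 ± 0.003 in the input of the CSR-1 strain, from 0.945 ± 0.005 to 0.342 ± 0.048 in that of the WAGO-9 strain and from 0.879 ± 0.011 to 0.233 ± 0.02 in the WAGO-9 IP. In that IP hpl-1 moved from 0.77 ± 0.003 to 0.625 ± 0.02 and the actin regulator gene eps-8 from 0.765 ± 0.044 to 0.266 ± 0.02. Toward the 3' end went mib-1 (0.178 ± 0.012 to 0.573 ± 0.02) and rib-1 (0.377 ± 0.035 to 0.699 ± 0.011) in the input of the CSR-1 strain, and noca-1 (0.196 ± 0.022 to 0.464 ± 0.069) and simr-1 (0.251 ± 0.005 to 0.514 ± 0.039) in the WAGO-9 IP. Shifts on hrde-1 and csr-1 were called in none of the 4 kinds of library.

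**Figure D3:**
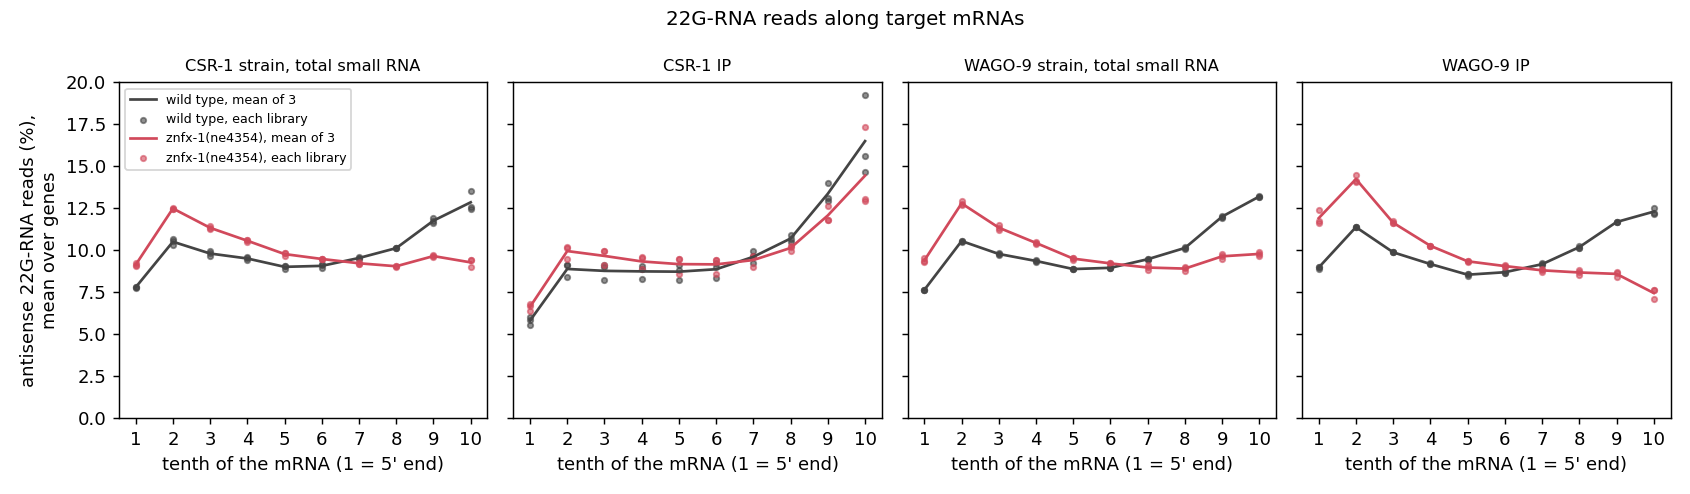
Percent of antisense 22G reads of a gene in each of 10 equal parts of its mRNA, averaged over genes, with points for libraries and lines for means of 3. In the WAGO-9 IP the part at the 3' end holds 12.3% in wild type and 7.46% in znfx-1.

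In the WAGO-9 IP 3445 of 5376 genes shifted toward the 5' end and 269 toward the 3' end, and the mean over genes moved from 0.518 ± 7e-04 to 0.451 ± 0.0054. The input of the WAGO-9 strain had 2202 and 158 of 4955 genes, with a mean moving from 0.532 ± 5e-04 to 0.483 ± 0.0019. The input of the CSR-1 strain had 2007 and 174 of 4876, from 0.529 ± 0.0043 to 0.483 ± 0.0016. For each of these means the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, and all 3 mutant libraries lay below all 3 wild-type ones. In the CSR-1 IP the mean was 0.571 ± 0.0164 in wild type and 0.545 ± 0.0164 in znfx-1 (exact permutation p = 0.3), with differences of −0.0261, −0.0275 and −0.0251 within the numbers 1 to 3. There 210 of 5108 genes shifted toward the 5' end, among them dys-1 (0.878 ± 0.028 to 0.216 ± 0.008) and egl-30 (0.621 ± 0.037 to 0.316 ± 0.058), and 13 toward the 3' end. This count of 223 was 794 with the replicate number as a block, 1 (dys-1) without wild-type replicate 2 or 3 or mutant replicate 2 or 3, 131 without mutant replicate 1 and 151 without wild-type replicate 1. Of WAGO-9-bound genes 66.2% shifted toward the 5' end in the WAGO-9 IP and of CSR-1-bound genes 58.9%, and 53.8% and 30% in the input of the CSR-1 strain. These shares were 58.1% and 23% in the input of the WAGO-9 strain. The CSR-1 IP had 77 of 630 WAGO-9-bound genes and 6 of 1832 CSR-1-bound genes shifted this way, with median shifts of −0.0483 and −0.0093.

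**Figure D4:**
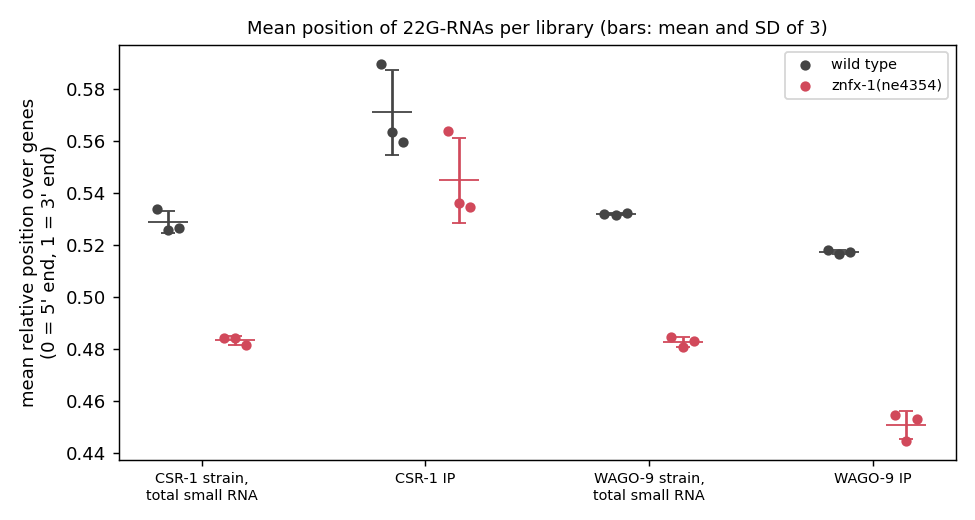
Mean position of antisense 22G-RNAs along target mRNAs over genes in each library, from 0 at the 5' end to 1 at the 3' end. The wild-type WAGO-9 IP lies at 0.518 and the mutant one at 0.451.

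Shifts were spread over most lists of the WAGO-9 IP. The counts toward the 5' and 3' end were 15 and 0 of 23 (15 and 0 adjusted over the list alone) for segregation genes such as air-2 (0.736 ± 0.009 to 0.56 ± 0.032) and 13 and 1 of 22 (13 and 1 adjusted over the list alone) for oogenesis genes. Nuclear RNAi factors such as set-2 (0.863 ± 0.011 to 0.695 ± 0.022) had 10 and 1 of 14 (10 and 1 adjusted over the list alone), and the set-2 call was lost with each distinct position counted only once (shift −0.044). Meiosis genes had 9 and 1 of 14 (9 and 1 adjusted over the list alone), with msh-5 moving from 0.461 ± 0.031 to 0.208 ± 0.05, and P granule factors 8 and 1 of 14 (8 and 1 adjusted over the list alone). Histones had 12 and 0 of 27 (12 and 0 adjusted over the list alone) and collagens 7 and 0 of 9 (7 and 0 adjusted over the list alone), with col-38 moving from 0.569 ± 0.018 to 0.32 ± 0.026. Neurons had 5 and 0 of 6 (5 and 0 adjusted over the list alone), reference loci 6 and 0 of 9 (6 and 0 adjusted over the list alone) and RdRP and Mutator factors 6 and 2 of 16 (6 and 2 adjusted over the list alone). Argonautes went both ways, 2 and 2 of 11 (0 and 2 adjusted over the list alone), with prg-1 (0.695 ± 0.015 to 0.794 ± 0.001) and nrde-3 (0.14 ± 0.011 to 0.258 ± 0.022) toward the 3' end.

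Other large shifts toward the 5' end were those of H11E01.3 (0.885 ± 0.011 to 0.343 ± 0.024), pix-1 and mpz-1 in the WAGO-9 IP and of iff-1 (0.675 ± 0.019 to 0.268 ± 0.051) and Y54E5A.2 in its input. In the input of the CSR-1 strain they were tmem-132 (0.81 ± 0.024 to 0.436 ± 0.015), ZC123.1 and the G protein gene egl-30 (0.663 ± 0.023 to 0.317 ± 0.003). Toward the 3' end went cla-1 (0.464 ± 0.043 to 0.767 ± 0.02) in the WAGO-9 IP, sox-4 (0.163 ± 0.018 to 0.483 ± 0.044) in its input, and glh-1 (0.359 ± 0.014 to 0.449 ± 0.019) in the input of the CSR-1 strain, a call lost with distinct positions (shift 0.009). In that input the counts were 7 and 0 of 16 (9 and 0 adjusted over the list alone) for nuclear RNAi factors and 5 and 0 of 6 (6 and 0 adjusted over the list alone) for collagens. Of the genes shifted toward the 5' end, 1229 were shared by the inputs (784.1 by chance) and 1748 by the WAGO-9 IP and its input (1258.9 by chance).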

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

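Tests of explanations in this part were written before their results were seen, except the splits of the libraries for the counts of level, the correlation against mutant CSR-1 IP libraries 2 and 3 and the block within each genotype, which were chosen only after the result was seen. Positions from sequences listed once were added after the shift was seen but before that test was run.

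The change in WAGO-9 enrichment (IP over input) between genotypes was tested directly and called 1222 genes, 379 with more enrichment in znfx-1 and 843 with less (2966 under an unadjusted p of 0.05; 1066 with limma voom). 22G-RNAs against znfx-1 went from input to IP in wild type as 361 ± 21.6 to 388 ± 5.79 and in the mutant as 108 ± 8.92 to 28 ± 4.15 (difference −2.02, adjusted p = 4e-05). hrde-1 (−0.83, adjusted p = 0.0166) and csr-1 (−0.903, adjusted p = 0.0092) also lost enrichment. Chosen after their values were seen, the microtubule gene cls-2 went from 919 ± 9.26 to 1113 ± 51.8 in wild type and from 405 ± 76.7 to 102 ± 16.7 in znfx-1, glh-4 from 383 ± 13.8 to 219 ± 18.7 and from 210.4 ± 17.7 to 30.1 ± 2.45, and the synaptic gene rpm-1 from 147 ± 10.1 to 14.5 ± 3.67 and from 84.1 ± 10.9 to 86.2 ± 23.6. The direction of most calls rests on the scaling: totals gave 1303 higher and 220 lower, median-of-ratios 565 and 561, and deposited values 1658 and 289. Without mutant WAGO-9 IP replicate 2 the count was 2387. Input and IP of the same number deviated together in the mutant, and the count was 1119 with the replicate number as a block and 1828 with such a block within each genotype.

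The CSR-1 enrichment differed between genotypes at 5 genes. For the kinase gene pkn-1 input and IP were 23.1 ± 0.471 to 77.1 ± 3.58 in wild type and 109 ± 5.31 to 95.97 ± 8.26 in znfx-1 (difference −1.88, adjusted p = 0.0104). The autophagy genes epg-2 (16.6 ± 1.51 to 57.8 ± 12.8 and 231 ± 5.18 to 204 ± 24.03) and atg-2 (29.5 ± 1.99 to 63.7 ± 5.92 and 184 ± 4.91 to 124 ± 17.2) also lost enrichment, as did K03A11.1 (−2.34), and Y54F10AM.11 gained it (1.65). All of these were chosen after their values were seen. With a replicate block within each genotype limma called 0 (655 under an unadjusted p of 0.05), and with a block shared by the genotypes 1. The count was 19 without wild-type CSR-1 IP replicate 1 and 0 to 2 without any 1 of the other 11 libraries.

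The effect of znfx-1 on total small RNA differed between the strains at 2921 genes, 1270 higher and 1651 lower in the WAGO-9 strain (4066 under an unadjusted p of 0.05). Deposited values turned the balance to 2570 higher and 1163 lower. In this fit of both inputs together over 11042 genes, 458 of the 2921 were called in opposite directions in the strains. Reads shared between near-identical genes are argued against as the whole cause, since 75.2% of the genes were also called with sequences listed once. Of the genes 74.2% differed between mutants and 62.7% between wild types (43.3% and 37.8% of all tested). Selection for this effect raises both, so a cause in the wild types alone stays open. The strains differ in their tagged Argonaute and in any background variant or culture, and these cannot be told apart because each strain was sampled with its own tag only. No biological explanation was tested, and a difference in culture or stage may contribute to the pattern.

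Shifts in position also differed between kinds of library: 350 genes between the WAGO-9 IP and its input (271 more toward the 5' end and 79 more toward the 3' end in the IP), and 218 genes between the inputs of the strains (120 and 98). With a replicate block within each kind of library, chosen after these results were seen, the splits were 172 and 45, and 84 and 80. Between the CSR-1 IP and its input limma called 0 of 4176 genes, with 270 under an unadjusted p of 0.05, and 1 and 2 genes with the block, with 754. Over these genes the mean shift was smaller in the IP than in the input within each number (−0.0295, −0.0305 and −0.0295 against −0.0483, −0.04 and −0.0442).

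The shift toward the 5' end was weighed against technical explanations. A few abundant positions per gene are argued against as the whole cause, since the mean in the WAGO-9 IP still differed by −0.0394 with each distinct position counted only once. Genes that gained or lost 22G-RNAs did not carry it alone, since genes with a level within 0.25 had median shifts of −0.0238 or lower in all 4 kinds of library. Assignment of repeated sequences to 1 position is argued against, since 71.7% of the shifted genes of the WAGO-9 IP were also called with sequences listed once. These values are consistent with a change in where 22G-RNAs are made or kept without ZNFX-1, which remains a hypothesis, found and tested on the same data.

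In the CSR-1 IP the libraries numbered 1 stood apart from those numbered 2 and 3 in both genotypes, with hrde-1 at 4428 against 633.5 and 510.5 RPM in wild type and 2511 against 579.3 and 553.9 in znfx-1. The chi-square per degree of freedom was 113.06 between wild-type libraries 1 and 2 and 14.71 between 2 and 3. Fewer reads are argued against, since libraries 1 and 2 still gave at least 35.69 after all were thinned to 1783668 reads. More unbound small RNA carried over in libraries 2 and 3 stays open. The planned correlation for it (r = 0.67 across genes) has a library numbered 1 on both sides, and the libraries numbered 1 of both genotypes deviate together, so it decides nothing. The correlation against mutant libraries 2 and 3 was 0.37. A mix of library 1 and input would lie between them: of 906 genes enriched in library 1, 0.6% and 0.3% lay below the wild-type input in libraries 2 and 3. Above library 1 lay 2.5% and 10.9%. Genes chosen as high in library 1 tend to lie between them anyway, so this decides nothing. Mutant WAGO-9 IP library 2 also stood apart, at 61.53 and 37.41 from libraries 1 and 3 against 8.3 between those, and no explanation of this was tested. Without it the WAGO-9 IP called 8744 genes in place of 6943. A shared preparation day for each number of the CSR-1 IP stays open, since the labels give none.

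Splitting 6 libraries into 3 and 3 gives 10 splits with the real one, too few for a share under 0.05. In all 8 comparisons between genotypes the others gave 0 calls. They mix the genotypes, which widens their spread, so this decides nothing. The real counts of level were 5914, 1227, 5324 and 6943 genes in the CSR-1 input, CSR-1 IP, WAGO-9 input and WAGO-9 IP, and those of position 2181, 223, 2360 and 3714.

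Reads outside the main measurement were also present. Sense 22-nt reads starting with G made up 2.8% of mapped reads in the mutant input of the CSR-1 strain (SD 0.0279, n = 3) and 2.68% in wild type (SD 0.0512). From wild type to znfx-1 the share went from 2.28% (SD 0.0945) to 2.01% (SD 0.0533) in the input of the WAGO-9 strain and from 1.93% (SD 0.0991) to 1.47% (SD 0.16) in its IP. In the CSR-1 IP it went from 1.81% (SD 0.401) to 1.97% (SD 0.232). Unmapped sequences, listed in IP files only, reached 33.13% of the listed reads in wild-type CSR-1 IP replicate 2 (95% Wilson interval 33.09% to 33.17%, counting error only), and their origin was not examined.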

How the results depend on the processing

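Chosen only after the result was seen were the tests with median-of-ratios scaling, deposited values, limma voom, pseudocounts of 0.25 and 5, positions from sequences listed once, the classes with an estimated correlation or a block, the block within each genotype or kind of library, and the CSR-1 IP libraries numbered 1 left out; all other alternatives were planned. For changes of value below, the cause was not tested unless given.

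A log2 fold of at least 1 leaves fewer genes by construction: 2458 in the CSR-1 input, 2384 in the WAGO-9 input, 4136 in the WAGO-9 IP and 553 for the change in WAGO-9 enrichment (1947 with deposited values). The CSR-1 IP called 783 genes with deposited values, 3680 with the replicate block and 2548 with the libraries numbered 1 left out. The change in CSR-1 enrichment (5 genes) became 3 with totals, 0 with deposited values, 0 with no filter, 1 with the block, 0 with a block within each genotype, 0 with sequences listed once, 1 with a pseudocount of 5 and 81 with the libraries numbered 1 left out.

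Leaving out 1 library at a time gave 5212 to 6026 genes for the CSR-1 input, 336 to 1288 for the CSR-1 IP, 4756 to 5360 for the WAGO-9 input and 5538 to 8744 for the WAGO-9 IP. IP against input gave 4964 to 6723 (wild type) and 4059 to 5850 (znfx-1) for CSR-1, and 8116 to 9243 and 8131 to 9199 for WAGO-9, with changes in enrichment at 0 to 19 and 828 to 2387 genes. Leaving out a library leaves 2 in its group, so fewer libraries enter the test by construction.

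Positions with at least 200 reads tested fewer genes, with 909, 118, 932 and 1646 shifted (CSR-1 input, CSR-1 IP, WAGO-9 input, WAGO-9 IP). With each distinct position counted only once, 1274, 1403 and 2381 shifted in the CSR-1 input, WAGO-9 input and WAGO-9 IP. For the CSR-1 IP the block gave 794, sequences listed once 144 and the libraries numbered 1 left out 658. The difference in mean position was −0.03 with distinct positions in the CSR-1 input. In the WAGO-9 input it was −0.0487 with at least 20 reads, −0.0505 with 200, −0.0311 with distinct positions, −0.0486 with reads pooled over genes and −0.0487 with sequences listed once. In the WAGO-9 IP it was −0.0646, −0.0649, −0.0394, −0.049 and −0.0686 in that order, and −0.07 for mRNAs of at least 1000 nt. Leave-one-out counts were 1616 to 1856, 1 to 151, 1933 to 2102 and 3371 to 3540, and differences −0.047 to −0.0431, −0.0357 to −0.0169, −0.0501 to −0.0482 and −0.0687 to −0.0638.

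The median of CSR-1-bound genes in the WAGO-9 input turned from −0.29 to 0.11 with deposited values (0.28 for all genes). It stayed at −0.29 (p = 0.102) with an estimated correlation, and leave-one-out gave −0.34 to −0.24. WAGO-9-bound genes gave 0.62 to 0.695. Of 15 lists, 0 were past the threshold with an estimated correlation in each comparison between genotypes, and in the CSR-1 IP 2 were with deposited values and 4 with the libraries numbered 1 left out. Leave-one-out gave 2 to 7 lists in the CSR-1 IP, 6 to 11 in the CSR-1 input, 8 to 10 in the WAGO-9 input and 9 to 10 in the WAGO-9 IP.

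Of 9866 values of named genes under alternatives, 9638 kept direction and side of the threshold, 156 lost the call, 65 gained it and 7 changed sign. With sequences listed once WAGO-9 IP against input gave pgl-3 0.12 and rps-26 −0.17 in wild type, and rps-26 −0.33 and sago-1 0.48 in znfx-1; deposited values gave col-111 0.19, col-60 0.18 and egl-21 0.084 in znfx-1. Of 2537 values of positions, 2311 kept both, 175 lost the call, 48 gained it and 3 changed sign: spe-47 was 0.066 with sequences listed once in the CSR-1 input and −0.025 with distinct positions in the WAGO-9 input, and F27B3.4 −0.016 with distinct positions in the WAGO-9 IP. For lists, 487 of 555 kept both, 37 lost the call and 31 gained it. The planned count-model test was not run; limma voom on the recovered reads took its place. Reads of other lengths or starts were not tested, since the files hold 22-nt sequences starting with G only. Depth was lowest in wild-type CSR-1 IP replicate 3 (1783668 reads), and 2-fold changes were recovered in 14% of simulated genes of that comparison.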

Other observations

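All tests in this part were chosen only after the result was seen, and all genes named in it were picked after their values were seen.

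Small RNAs against the heat-shock genes hsp-16.48 and hsp-16.49, which encode near-identical small chaperones, went opposite ways in the strains. In the input of the CSR-1 strain hsp-16.48 went from 29.1 ± 5.68 to 7.28 ± 5.09 in wild type to znfx-1, and in that of the WAGO-9 strain from 3.02 ± 0.7303 to 68.8 ± 45.9; for hsp-16.49 the values were 24.2 ± 5.52 to 5.25 ± 4.83 and 2.85 ± 1.395 to 49.5 ± 32.6. The xanthine dehydrogenase gene xdh-1 was 3.46 ± 1.18 to 5.05 ± 0.554 in the CSR-1 strain and 79.6 ± 1.75 to 2771 ± 753 in the WAGO-9 strain. The cathepsin gene cpz-1 was 165 ± 12.3 to 77.5 ± 5.2 and 5.33 ± 1.08 to 69.3 ± 14.8, and the galectin gene lec-2 1.17 ± 0.525 to 10.6 ± 2.104 and 20.2 ± 11.9 to 1.55 ± 0.148. C51E3.9, among the largest gains of the CSR-1 strain at 0.944 ± 0.554 to 71.1 ± 7.43, was 9.11 ± 0.897 to 6.73 ± 0.561 in the WAGO-9 strain.

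Sense reads, which match the mRNA strand, were also counted per gene. In the input of the CSR-1 strain F37H8.2 had 340.5 sense RPM of the library total in wild type and 449.4 in znfx-1, and the chemoreceptor gene srh-48 had 179.8 and 216.8. Sense reads of srh-48 in the WAGO-9 IP were 374.7 and 123.3. math-49 had 73.37 and 268.7 in the input of the WAGO-9 strain.

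The share of antisense 22G reads in the library was 30.3% (SD 1.19) in the wild-type WAGO-9 IP and 36.1% (SD 1.21) in znfx-1, and 15.7% (SD 0.985) and 20.1% (SD 1.86) in its input. Unmapped sequences made up 32.8% (SD 0.153) and 25.5% (SD 1.13) of the listed reads of that IP.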
